A study of Homo sapiens with 24 samples.

How the data were processed

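Total RNA of sorted viable GFP-positive cells from OCI-Ly18 and SU-DHL-4, made into libraries with the NEBNext Ultra II kit per the labels, was measured by bulk RNA sequencing in 24 libraries, 3 in each of 8 groups: 2 lines, DMSO or 500 nM tazemetostat, UTD or CART19 cells. The pretreatment lasted 72 h and the culture with T cells 48 h. The labels do not spell out UTD. The values are counts per gene and library, deposited by the authors as whole numbers that are not scaled. Per the submitters' processing notes the genome build was hg38 and DESeq2 was used. Versions, the aligner, the counting tool and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes may be mixed. All 58735 gene IDs of the table match GENCODE release 29 with the same start and end, 35075 had at least 1 count, and 27 gene names that had been turned into dates were restored from the IDs. Rows that name no gene and unused columns of other per-sample values numbered 0 each. A second sheet gives each library's replicate number. Raw reads were not used here.

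Libraries held 14.8e6 to 20.1e6 counts. Replicates were checked against duplication: the chi-square of 2 replicates over its degrees of freedom, for genes with at least 20 counts in both, was 2.77 to 13.1 over 24 pairs, where copies of one library would give about 1 or less. Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM factors, filterByExpr by group, and a robust quasi-likelihood fit and F-test. Each line was fitted on its own (12 libraries, 4 groups, 8 residual degrees of freedom), with contrasts for tazemetostat with UTD and with CART19 cells, CART19 under DMSO and under tazemetostat, and their interaction. Differences between the lines were tested in one fit of all 24 libraries (16 residual degrees of freedom). The common biological coefficient of variation was 0.0855, 0.0729 and 0.0801 in OCI-Ly18, SU-DHL-4 and the joint fit, and TMM factors ran from 0.974 to 1.04, 0.972 to 1.03 and 0.956 to 1.06. P-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05. Standard errors are those of the fitted log2 fold change. No outlier rule was applied, since groups of 3 are not tested.

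The 28 gene lists came from textbook knowledge. Each was tested with limma 3.58.1 camera (correlation 0.01, log2 CPM with prior count 2), adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Effects were correlated only between contrasts that share no library. The genes named were set by a rule: (1) among protein coding genes that passed, had at least 5 CPM in the higher group and, between 2 groups, replicates that did not overlap, the 6 largest increases and 4 largest decreases, or 4 and 4 for interactions and line differences; (2) up to 4 members of each list described, by absolute log2 fold change among those that passed; (3) anchor genes such as EZH2, MS4A1, CD274, B2M, CIITA, FAS, CD58, ICAM1, PRDM1, BCL6, IRF4, CDKN1A and IRF1. Names outside the rule are marked in the text, and some genes that the rule picks are not reported here. Where a group had no counts, a fold is a bound that sets 3 counts over the group, and where it had 1 to 3 counts a ratio with a 95% counting interval is given in place of the fitted fold.

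The method was tested on simulated data made from each gene's mean over the libraries, its spread and the library sizes, with 200 of 16467, 14861 or 17766 genes changed 1.5, 2 or 4 fold. For tazemetostat with UTD cells in OCI-Ly18, 47.8%, 64.2% and 89.2% of the genes changed 1.5, 2 and 4 fold were called. There 11.3% of 150 calls were false, the highest. For the interaction in SU-DHL-4 8.80% of 125 were false, and for tazemetostat with CART19 between the lines 1.98% of 101, the lowest. One planted list was called each time and 0 of 27 others. Neither correlated lists nor interactions beside other effects were simulated.

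Alternatives planned ahead were RLE and upper quartile scaling, no filter and a stricter filter on low counts (at least 1 CPM in all 3 libraries of a group and a mean of 20 counts), DESeq2 1.42.0 and limma voom, fits of the groups compared alone or of all 24 libraries, a minimum of 1 log2, and each library left out in turn. Added after seeing the data were the authors' replicate number as a block, trends with gene length and GC content removed within each library (splines with 4 degrees of freedom), and TAZ CART19 replicates 1 and 2 left out. Libraries were regrouped within each comparison, at most 100 splits each. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.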

Results

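Bulk RNA was sequenced from 24 libraries of 2 established human B cell lymphoma lines, OCI-Ly18 and SU-DHL-4. The tumour cells had been kept for 72 h in 500 nM tazemetostat, an inhibitor of the histone methyltransferase EZH2, or in DMSO, and then for 48 h with CART19 cells or with UTD cells. Viable GFP-positive tumour cells were sorted from each culture. Each of the 8 groups held 3 libraries of 14.8e6 to 20.1e6 counts (median 16.6e6). Parentheses after a gene give its log2 fold change ± standard error and its adjusted p (edgeR quasi-likelihood test, 3 libraries per group), and a level is a mean ± SD in counts per 1e6 counts (CPM). The gene lists were fixed before the data were examined, and after the counts of a list stand the members that rose and fell with p adjusted over the list alone and the list's camera adjusted p. A camera call held with an estimated correlation unless a second p is given. For each gene given as a largest change between 2 groups, replicates did not overlap, which chance allows for 10% of genes with 3 libraries against 3. The p-values measure spread between libraries, which may be technical, because the labels do not state whether replicates were cultured independently.

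Some T cell transcripts were scarce in the sorted cells, while TRAC was at 18.4 to 39.9 CPM in every group and TRBC2 at 60.7 to 79 CPM in those of OCI-Ly18. CD3D, CD3G, CD2 and CD7, surface proteins of T cells that were chosen from a fixed list after their values were seen, summed to 13 counts over the 6 CART19 libraries of OCI-Ly18 against 0 over its 6 UTD libraries, and to 7 against 12 in SU-DHL-4. The T cell products IFNG and GZMB, chosen likewise, summed to 154 counts with CART19 against 0 with UTD cells in OCI-Ly18, and to 153 against 5 in SU-DHL-4. With DMSO CART19 and TAZ CART19, IFNG had 43 and 72 counts in OCI-Ly18, and 16 and 77 in SU-DHL-4, the 77 with up to 47 in 1 library. GZMB had 20 and 19 counts in OCI-Ly18, and 21 and 39 in SU-DHL-4. CD3E gave 6, 0, 4 and 5 counts in the OCI-Ly18 groups DMSO UTD, TAZ UTD, DMSO CART19 and TAZ CART19, and 193, 155, 118 and 158 in SU-DHL-4. CD8A gave 39, 63, 61 and 45 counts in the same order in OCI-Ly18, and 0, 0, 0 and 5 in SU-DHL-4. EZH2 (ENSG00000106462, GRCh38 chromosome 7, 148807383 to 148884321), the target of the drug, fell slightly with tazemetostat in OCI-Ly18, by 0.24 ± 0.052 log2 with UTD cells (adjusted p = 0.000967) and by 0.23 ± 0.052 with CART19 (adjusted p = 0.00121). It fell in SU-DHL-4 by 0.28 ± 0.049 (adjusted p = 9.16e-06) and 0.19 ± 0.049 (adjusted p = 0.00163), the latter not past the threshold with upper quartile scaling (log2 -0.11).

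**Figure D1:**
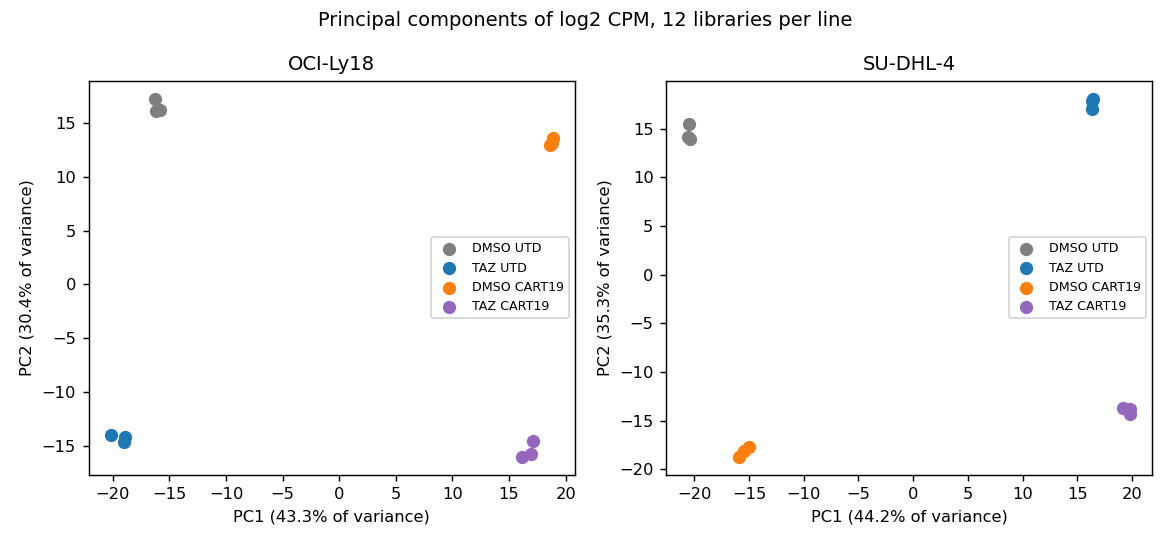
Principal components of log2 CPM for the 12 libraries of each line, PC1 against PC2 with the percent of variance on each axis and 1 point per library. PC1 held 43.3% of the variance in OCI-Ly18 and separated CART19 from UTD libraries, and held 44.2% in SU-DHL-4 and separated tazemetostat from DMSO libraries.

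With UTD cells, tazemetostat raised 1916 genes and lowered 2090 in OCI-Ly18, of 16467 tested. Upper quartile scaling gave 2145 and 1699. Among changes of at least 1 log2, 554 were increases and 65 decreases. The largest increases were NME4 (3.06 ± 0.22, 8.9e-11), LRP5 (2.67 ± 0.31, 7.7e-08), SLC25A29 (2.44 ± 0.17, 4.1e-12), KCNJ12 (2.41 ± 0.14, 2.1e-12), ASAP2 (2.35 ± 0.33, 2.2e-06) and ZNF74 (2.35 ± 0.42, 3.4e-04). NME4 encodes a mitochondrial nucleoside diphosphate kinase and LRP5 a Wnt coreceptor. The largest decreases were ASB2 (-1.71 ± 0.26, 1.3e-04), SUSD3 (-1.68 ± 0.28, 2.9e-05), NPAS2 (-1.65 ± 0.23, 1.4e-06) and APOL6 (-1.58 ± 0.13, 8.6e-11), of which APOL6 belongs to a family of similar genes whose reads may be shared. Of the 12 measured PRC2 subunits, 3 rose, 5 fell and 4 did not pass (3 and 5 over the list alone, camera adjusted p = 0.592, median -0.047, mean 0.036, test direction down). EPOP (1.02 ± 0.15, 2.0e-05) and JARID2 (0.51 ± 0.074, 4.4e-06) were higher and SUZ12 (-0.33 ± 0.064, 4.8e-04) and RBBP7 (-0.31 ± 0.051, 2.2e-05) lower. Among 19 measured developmental transcription factors known as Polycomb targets, 6 rose, 1 fell and 12 did not pass (6 and 1 over the list alone, camera adjusted p = 0.0391, adjusted p = 0.256 with an estimated correlation). SOX2 (2.86 ± 0.65, 0.0013), GATA4 (1.98 ± 0.48, 0.0023) and HOXA10 (1.55 ± 0.34, 8.2e-04) were among them. That call was lost without DMSO UTD replicate 2 (adjusted p = 0.159), TAZ UTD replicate 1 (adjusted p = 0.0904) or TAZ CART19 replicate 2 (adjusted p = 0.0577).

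Most cell cycle genes of OCI-Ly18 fell with the drug. The 39 measured G1/S and DNA replication genes gave 0 that rose, 33 that fell and 6 that did not pass (0 and 36 over the list alone, camera adjusted p = 6.2e-14). The histone mRNA binding protein gene SLBP (-0.42 ± 0.052, 3.0e-07) and the replicative helicase subunit gene MCM6 (-0.40 ± 0.048, 1.3e-07) were among them. For G2/M and mitosis genes, 38 measured, 0 rose, 34 fell and 4 did not pass (0 and 36 over the list alone, camera adjusted p = 1.8e-17), among them PTTG1 (-0.58 ± 0.080, 1.6e-06), ECT2 (-0.55 ± 0.070, 4.1e-07) and CENPE (-0.55 ± 0.070, 1.7e-06), which encode securin, a cytokinesis regulator and a kinetochore motor. Of the 24 measured cholesterol synthesis genes, 0 rose, 10 fell and 14 did not pass (1 and 10 over the list alone, camera adjusted p = 6.9e-05). The sterol isomerase gene EBP (-0.50 ± 0.090, 9.2e-05), ACAT2 (-0.46 ± 0.069, 7.7e-06) and the HMG-CoA synthase gene HMGCS1 (-0.45 ± 0.057, 4.6e-07) were among them. Among 31 measured MYC target genes, 2 rose, 11 fell and 18 did not pass (2 and 12 over the list alone, camera adjusted p = 0.0182, adjusted p = 0.119 with an estimated correlation), while MYC (0.67 ± 0.044, 7.6e-13) itself rose. B cell state genes moved in both directions. The 27 measured germinal centre genes gave 7 that rose, 9 that fell and 11 that did not pass (7 and 9 over the list alone, camera adjusted p = 0.429, median -0.046, mean 0.012, test direction down). SERPINA9 (2.49 ± 0.46, 1.1e-04) and MEF2C (0.95 ± 0.11, 4.7e-08) were higher. The plasma cell regulators PRDM1 (1.41 ± 0.34, 0.0023) and IRF4 (0.74 ± 0.058, 2.6e-11) rose and the memory marker CD27 (-1.37 ± 0.13, 1.5e-09) fell, as did MS4A1 (-0.20 ± 0.048, 0.0016), which encodes CD20. CDKN1A (0.15 ± 0.092, 0.269) did not pass. The class II regulator CIITA (0.39 ± 0.050, 7.0e-07), HLA-DOA (0.43 ± 0.056, 7.6e-07), the galectin gene LGALS9 (1.96 ± 0.21, 1.3e-08) and the p53 target TP53INP1 (1.57 ± 0.12, 1.6e-11) rose.

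In SU-DHL-4 with UTD cells, tazemetostat raised 2561 genes and lowered 2721, of 14861 tested. With upper quartile scaling 3221 rose and 1782 fell, 64.4% in place of 48.5% rising, and a fit of all 24 libraries gave 2768 and 2196. Among changes of at least 1 log2, 1006 were increases and 27 decreases. The largest increases were SYNPO (4.53 ± 0.38, 3.2e-13), FCER2 (3.68 ± 0.25, 4.4e-16), ZNF467 (3.18 ± 0.23, 6.0e-14), BACH2 (3.16 ± 0.13, 2.7e-23), JAM2 (3.13 ± 0.34, 3.0e-10) and CYS1 (2.94 ± 0.33, 7.8e-10). FCER2 encodes the IgE receptor CD23 of B cells and BACH2 a repressor of plasma cell fate. The largest decreases were ZNF25 (-1.04 ± 0.25, 7.6e-04), HTR3A (-1.01 ± 0.048, 1.5e-21), COL24A1 (-0.91 ± 0.24, 0.0026) and CGAS (-0.87 ± 0.24, 0.0032), where CGAS encodes the cytosolic DNA sensor and lost its call without DMSO UTD replicate 1 (adjusted p = 0.0879). For PRC2 subunits, 12 measured, 3 rose, 6 fell and 3 did not pass (3 and 7 over the list alone, camera adjusted p = 0.112). EPOP (0.63 ± 0.097, 9.8e-06) and EZH1 (0.45 ± 0.081, 1.6e-05) were higher and SUZ12 (-0.33 ± 0.059, 1.8e-05) and RBBP7 (-0.36 ± 0.053, 3.9e-07) lower.

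HLA-B led the antigen presentation genes that rose in SU-DHL-4 with the drug. HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188) went from 7.83 ± 0.558 to 31.8 ± 3.09 CPM (2.02 ± 0.082, 8.2e-24). The gene of the class I transactivator, NLRC5 (ENSG00000140853, chromosome 16, 56989485 to 57083531, 1.67 ± 0.11, 2.3e-16), the peptide transporter gene TAP1 (0.43 ± 0.069, 2.5e-06) and HLA-E (0.40 ± 0.051, 1.6e-08) also rose. Of the 20 measured MHC class I genes, 7 rose, 6 fell and 7 did not pass (7 and 8 over the list alone, camera adjusted p = 0.440). Among 19 measured MHC class II genes, 12 rose, 0 fell and 7 did not pass (13 and 0 over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.0502 with an estimated correlation). HLA-DOA (0.80 ± 0.052, 1.0e-16), HLA-DOB (0.53 ± 0.10, 4.8e-05), HLA-DMB (0.51 ± 0.071, 1.5e-07) and CIITA (0.34 ± 0.058, 7.4e-06) were among them. Reads may be shared between HLA genes. The 27 measured B cell identity genes gave 13 that rose, 3 that fell and 11 that did not pass (13 and 3 over the list alone, camera adjusted p = 0.0180, adjusted p = 0.0502 with an estimated correlation). CD24 (2.26 ± 0.17, 3.2e-14), FCGR2B (1.36 ± 0.14, 1.6e-10) and MS4A1 (0.24 ± 0.043, 1.5e-05) were among them. For inhibitory ligands and receptors, 13 measured, 7 rose, 1 fell and 5 did not pass (7 and 1 over the list alone, camera adjusted p = 0.0275, adjusted p = 0.0632 with an estimated correlation), with LGALS9 (2.16 ± 0.27, 1.4e-08) and CEACAM1 (3.53 ± 0.54, 7.9e-07), and VSIR, which encodes the checkpoint protein VISTA, at least 33.8-fold above a group with no counts. That call was lost without TAZ UTD replicate 2 (adjusted p = 0.0556) or TAZ CART19 replicate 2 (adjusted p = 0.0522). SLAMF7 (4.33 ± 0.54, 1.2e-08) rose, and CD44 rose 34.6-fold (95% counting interval 9.25 to 291).

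Proliferation genes of SU-DHL-4 fell with the drug. Of the 39 measured G1/S and DNA replication genes, 0 rose, 36 fell and 3 did not pass (0 and 37 over the list alone, camera adjusted p = 4.3e-20). E2F2 (-0.76 ± 0.055, 3.9e-15) and CDC45 (-0.65 ± 0.071, 3.0e-10) were among them. Among 38 measured G2/M and mitosis genes, 0 rose, 37 fell and 1 did not pass (0 and 37 over the list alone, camera adjusted p = 1.4e-16), among them PTTG1 (-0.65 ± 0.061, 7.5e-12), CCNA2 (-0.58 ± 0.049, 4.0e-13) and AURKA (-0.57 ± 0.060, 1.4e-10), which encode securin, cyclin A2 and Aurora A. The 31 measured MYC targets gave 0 that rose, 24 that fell and 7 that did not pass (1 and 26 over the list alone, camera adjusted p = 4.2e-09). POLR3G (-0.68 ± 0.073, 2.9e-10), LYAR (-0.67 ± 0.061, 3.3e-12) and MRTO4 (-0.51 ± 0.051, 3.9e-11) were among them. For cholesterol synthesis genes, 24 measured, 1 rose, 16 fell and 7 did not pass (1 and 17 over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.0502 with an estimated correlation). HMGCS1 (-0.53 ± 0.051, 2.3e-11), IDI1 (-0.47 ± 0.052, 5.7e-10) and EBP (-0.43 ± 0.074, 1.0e-05) were among them. Of the 22 measured heat shock and oxidative stress genes, 3 rose, 14 fell and 5 did not pass (3 and 15 over the list alone, camera adjusted p = 2.2e-04). Among 24 measured p53 targets, 7 rose, 5 fell and 12 did not pass (7 and 6 over the list alone, camera adjusted p = 0.570), where the CDK inhibitor p21 gene CDKN1A (1.47 ± 0.15, 5.6e-10), SESN1 (2.04 ± 0.17, 3.8e-13) and TP53INP1 (1.59 ± 0.12, 7.3e-15) rose.

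**Figure D2:**
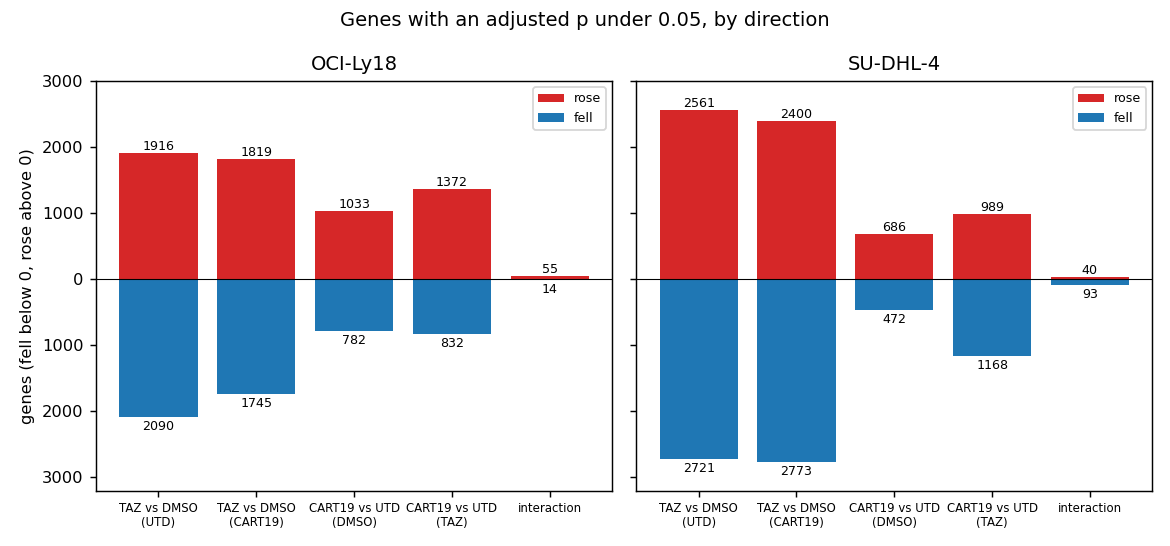
Number of genes with an adjusted p under 0.05 in each comparison and line, with increases drawn above 0 and decreases below 0. The bars run from 69 genes for the interaction in OCI-Ly18 (55 up, 14 down) to 5282 for tazemetostat with UTD cells in SU-DHL-4 (2561 up, 2721 down).

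With CART19 cells, tazemetostat raised 1819 genes and lowered 1745 in OCI-Ly18, of which 424 and 68 changed by at least 1 log2. Decreases were more numerous with limma voom (1737 rose and 1816 fell), with no filter (1639 and 1846), without DMSO CART19 replicate 2 (1432 and 1434) or TAZ CART19 replicate 2 (1872 and 2015), and in 2 settings added after seeing the data, with trends with length and GC content removed (1928 and 2327) and without TAZ CART19 replicates 1 and 2 (1195 and 1382). NME4 (2.83 ± 0.21, 2.6e-10), LRP5 (2.75 ± 0.32, 8.7e-08), BEND7 (2.39 ± 0.29, 2.5e-07), KCNJ12 (2.39 ± 0.14, 1.0e-12), KCNMA1 (2.32 ± 0.29, 3.9e-07) and SLC9A5 (2.27 ± 0.30, 1.1e-06) rose most. CEBPD (-1.47 ± 0.21, 2.5e-06), NDUFA4L2 (-1.35 ± 0.24, 7.0e-05), CD27 (-1.34 ± 0.13, 3.3e-09) and ASB2 (-1.28 ± 0.21, 3.4e-04) fell most. The 39 measured G1/S and DNA replication genes gave 0 that rose, 33 that fell and 6 that did not pass (0 and 37 over the list alone, camera adjusted p = 2.4e-18). The DNA primase gene PRIM1 (-0.56 ± 0.11, 2.6e-04) and CDC45 (-0.49 ± 0.070, 2.6e-06) were among them. For G2/M and mitosis genes, 38 measured, 1 rose, 33 fell and 4 did not pass (1 and 35 over the list alone, camera adjusted p = 6.5e-18). AURKA (-0.62 ± 0.063, 7.4e-09) and PTTG1 (-0.56 ± 0.080, 2.8e-06) were among them. Of the 24 measured cholesterol synthesis genes, 0 rose, 15 fell and 9 did not pass (0 and 15 over the list alone, camera adjusted p = 4.1e-06). EBP (-0.43 ± 0.088, 4.9e-04) was among them. Among 34 measured unfolded protein and integrated stress response genes, 3 rose, 17 fell and 14 did not pass (3 and 19 over the list alone, camera adjusted p = 3.9e-06). The cystine transporter gene SLC7A11 (-1.0 ± 0.18, 6.2e-05) and ATF5 (-0.66 ± 0.060, 8.4e-10) were among them. The 31 measured MYC targets gave 1 that rose, 12 that fell and 18 that did not pass (1 and 15 over the list alone, camera adjusted p = 8.6e-05), with MYC (0.52 ± 0.044, 1.3e-10) itself higher. For p53 targets, 27 measured, 8 rose, 2 fell and 17 did not pass (8 and 2 over the list alone, camera adjusted p = 0.0278, adjusted p = 0.0681 with an estimated correlation). TP53INP1 (1.92 ± 0.12, 1.0e-13) and BTG2 (0.80 ± 0.055, 1.6e-12) were among them. The call of the p53 list was lost without TAZ CART19 replicate 2 (adjusted p = 0.0753). Of the 13 measured mitochondrially encoded mRNAs, 4 rose, 0 fell and 9 did not pass (5 and 0 over the list alone, camera adjusted p = 0.0330, adjusted p = 0.501 with an estimated correlation), a call lost without DMSO CART19 replicate 1 (adjusted p = 0.0938) or 3 (adjusted p = 0.0909) or TAZ CART19 replicate 3 (adjusted p = 0.0915).

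In SU-DHL-4 with CART19 cells, 2400 genes rose with tazemetostat and 2773 fell. Upper quartile scaling gave 3106 and 1715, 64.4% in place of 46.4% rising. Increases were also more numerous in a fit of all 24 libraries (2633 and 2180), with only the groups compared (2336 and 2304) and without DMSO UTD replicate 1 (2647 and 2440) or 3 (2611 and 2445), TAZ UTD replicate 1 (2562 and 2354) or 3 (2540 and 2343) or DMSO CART19 replicate 3 (2223 and 2026). The largest increases were ZNF467 (4.09 ± 0.26, 2.2e-15), SYNPO (3.91 ± 0.33, 5.0e-13), BACH2 (3.34 ± 0.14, 2.9e-23), JAM2 (3.11 ± 0.33, 2.9e-10), ANXA4 (3.03 ± 0.31, 1.2e-10) and CORO2A (2.87 ± 0.21, 6.7e-15), and the largest decreases HTR3A (-1.16 ± 0.048, 2.9e-23), LTA (-1.11 ± 0.096, 1.0e-12), SGK1 (-1.0 ± 0.18, 1.5e-05) and TRIP10 (-0.93 ± 0.18, 3.8e-05), where LTA encodes lymphotoxin alpha. Among 20 measured MHC class I genes, 5 rose, 5 fell and 10 did not pass (5 and 5 over the list alone, camera adjusted p = 0.767, median -0.046, mean 0.035, test direction down). HLA-B (0.47 ± 0.050, 2.4e-10), HLA-C (0.55 ± 0.076, 2.0e-07) and NLRC5 (0.46 ± 0.063, 1.3e-07) were higher, and HLA-DOA (0.73 ± 0.050, 8.9e-16) of class II also rose. The 36 measured type I interferon response genes gave 14 that rose, 4 that fell and 18 that did not pass (16 and 4 over the list alone, camera adjusted p = 0.0069). IFI44L (1.70 ± 0.31, 1.9e-05) and IFI6 (1.42 ± 0.28, 6.0e-05) were among them. For inhibitory ligands and receptors, 13 measured, 6 rose, 1 fell and 6 did not pass (8 and 1 over the list alone, camera adjusted p = 0.0206, adjusted p = 0.0681 with an estimated correlation). VSIR (4.70 ± 0.63, 7.9e-08) and LGALS9 (2.38 ± 0.20, 2.9e-13) were among them. Of the 39 measured G1/S and DNA replication genes, 0 rose, 36 fell and 3 did not pass (0 and 36 over the list alone, camera adjusted p = 1.6e-20). E2F2 (-0.90 ± 0.056, 3.5e-17) and the thymidylate synthase gene TYMS (-0.69 ± 0.084, 6.3e-09) were among them. Among 38 measured G2/M and mitosis genes, 0 rose, 35 fell and 3 did not pass (0 and 38 over the list alone, camera adjusted p = 2.0e-17). CCNB2 (-0.58 ± 0.059, 9.0e-11) and AURKB (-0.57 ± 0.072, 2.8e-08) were among them. HMGCS1 (-0.60 ± 0.051, 6.1e-13), the ribosome biogenesis gene LYAR (-0.64 ± 0.061, 1.6e-11) and the amino acid transporter genes SLC7A5 (-0.73 ± 0.045, 4.2e-17) and SLC7A11 (-0.64 ± 0.099, 1.0e-06) fell, while CDKN1A (1.21 ± 0.15, 1.9e-08) and SESN1 (2.08 ± 0.17, 2.3e-13) rose. The 13 measured mitochondrially encoded mRNAs gave 9 that rose, 0 that fell and 4 that did not pass (9 and 0 over the list alone, camera adjusted p = 0.0080, adjusted p = 0.338 with an estimated correlation).

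CART19 cells, compared with UTD cells under DMSO, raised 1033 genes and lowered 782 in OCI-Ly18. Decreases were more numerous with upper quartile scaling (877 rose and 942 fell) and, in a setting added after seeing the data, with trends with length and GC content removed (1031 and 1072). Interferon-induced genes led: GBP4 (ENSG00000162654, chromosome 1, 89181148 to 89198932) rose (9.47 ± 0.11, 3.5e-35), and GBP1 (8.56 ± 0.10, 5.0e-35), GBP2 (7.74 ± 0.32, 4.4e-19) and EPSTI1 (5.48 ± 0.27, 4.0e-17) rose as well. GBP1 went from 1.28 ± 0.513 to 476 ± 7.37 CPM, ETV7 rose at least 121-fold from a group with no counts, and SLFN12L rose 126-fold (95% counting interval 42.8 to 613). Such counting intervals and bounds cover counting error only, and GBP paralogs may share reads. The largest decreases were CDHR3 (-1.97 ± 0.16, 2.6e-11), RASSF6 (-1.56 ± 0.073, 1.0e-17), NPAS2 (-1.52 ± 0.22, 6.5e-06) and BEST3 (-1.45 ± 0.093, 7.5e-14). For interferon gamma response genes, 34 measured, 30 rose, 0 fell and 4 did not pass (31 and 0 over the list alone, camera adjusted p = 1.0e-54). IRF1 (3.10 ± 0.066, 1.9e-27) was among them. Of the 39 measured type I interferon response genes, 33 rose, 0 fell and 6 did not pass (36 and 1 over the list alone, camera adjusted p = 4.2e-41). IFI44L (5.12 ± 0.47, 5.5e-10) was among them. In this comparison IFNG had 43 counts and GZMB 20 with DMSO CART19, and 0 each with DMSO UTD. The rest of this line's 154 counts lay in its TAZ CART19 libraries, IFNG with 72 and GZMB with 19.

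Antigen presentation genes of OCI-Ly18 rose with CART19. Among 21 measured MHC class I genes, 21 rose and 0 fell (21 and 0 over the list alone, camera adjusted p = 4.2e-41), among them TAP1 (3.24 ± 0.054, 1.4e-30), HLA-F (3.06 ± 0.18, 5.3e-14), PSMB9 (2.37 ± 0.071, 3.4e-23), HLA-E (1.78 ± 0.056, 1.9e-22) and B2M (1.51 ± 0.043, 6.6e-24), the latter from 438 ± 16.9 to 1249 ± 12.9 CPM. The 20 measured MHC class II genes gave 16 that rose, 0 that fell and 4 that did not pass (17 and 0 over the list alone, camera adjusted p = 2.3e-18). CIITA (0.67 ± 0.050, 3.8e-12), HLA-DQA1 (0.96 ± 0.054, 2.5e-15) and HLA-DPB1 (0.86 ± 0.074, 5.8e-09) were among them. For NF-kB targets, 25 measured, 11 rose, 0 fell and 14 did not pass (11 and 0 over the list alone, camera adjusted p = 4.5e-05). BCL3 (1.20 ± 0.12, 5.1e-09) and BCL2A1, an antiapoptotic gene, up 41.2-fold (95% counting interval 7.03 to 1670) were among them. Of the 22 measured adhesion and costimulatory ligands, 9 rose, 0 fell and 13 did not pass (9 and 2 over the list alone, camera adjusted p = 3.3e-04). ICAM1 (2.03 ± 0.15, 3.6e-12) was among them. Among 13 measured inhibitory ligands and receptors, 5 rose, 0 fell and 8 did not pass (5 and 0 over the list alone, camera adjusted p = 9.4e-05). TNFRSF14 (4.22 ± 0.39, 1.6e-08) and LGALS9 (2.69 ± 0.20, 1.7e-12) were higher, whereas CD274 (0.32 ± 0.37, 0.679), which encodes PD-L1, did not pass. The 32 measured death receptor and apoptosis regulators gave 12 that rose, 1 that fell and 19 that did not pass (13 and 2 over the list alone, camera adjusted p = 6.4e-05). The death receptor gene FAS (1.94 ± 0.14, 1.3e-12) and the survival kinase gene PIM2 (1.41 ± 0.064, 5.3e-18) were higher.

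Beyond the interferon lists, some B cell genes of OCI-Ly18 changed with CART19. For B cell identity genes, 27 measured, 10 rose, 3 fell and 14 did not pass (12 and 4 over the list alone, camera adjusted p = 7.1e-04), among them BANK1 (1.28 ± 0.18, 1.9e-06) and PTPN6 (1.63 ± 0.27, 5.8e-05), while the germinal centre regulator BCL6 (-0.045 ± 0.050, 0.667) did not pass. Of the 24 measured cholesterol synthesis genes, 6 rose, 0 fell and 18 did not pass (13 and 0 over the list alone, camera adjusted p = 5.5e-06). MVD (0.49 ± 0.094, 3.8e-04) and DHCR7 (0.28 ± 0.065, 0.0034) were among them. Among 34 measured unfolded protein and integrated stress response genes, 15 rose, 3 fell and 16 did not pass (19 and 3 over the list alone, camera adjusted p = 2.6e-06). ATF3 (1.31 ± 0.26, 7.1e-04) was among them. The 38 measured G2/M and mitosis genes gave 0 that rose, 11 that fell and 27 that did not pass (0 and 19 over the list alone, camera adjusted p = 1.2e-06). CKAP2L (-0.39 ± 0.087, 0.0022) and ASPM (-0.29 ± 0.064, 0.0023) were among them. The number of changed genes was 1815, and it was 1187 without DMSO UTD replicate 2, 1206 without DMSO CART19 replicate 1 and 1199 without DMSO CART19 replicate 3.

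In SU-DHL-4 under DMSO, CART19 raised 686 genes and lowered 472. With trends with gene length and GC content removed, a setting chosen after seeing the data, 47.5% of the changed genes rose in place of 59.2%, and without TAZ CART19 replicates 1 and 2, chosen likewise, 49.4%. GBP4 rose at least 486-fold and the chemokine gene CCL25 at least 99.2-fold from groups with no counts, SAMD9L rose 235-fold (95% counting interval 64.8 to 1950), and GBP1 (9.26 ± 0.17, 1.0e-39), LGALS3BP (6.19 ± 0.24, 3.3e-18) and PARP14 (5.60 ± 0.30, 1.0e-15) rose too. Among the largest decreases were HEMGN (-2.66 ± 0.28, 2.5e-10), S100A4 (-1.31 ± 0.18, 3.6e-07) and OPRL1 (-1.14 ± 0.23, 0.0011). For interferon gamma response genes, 32 measured, 27 rose, 0 fell and 5 did not pass (28 and 0 over the list alone, camera adjusted p = 3.7e-50). IRF1 (4.15 ± 0.12, 9.2e-15) was among them. Of the 36 measured type I interferon response genes, 34 rose, 0 fell and 2 did not pass (35 and 0 over the list alone, camera adjusted p = 6.2e-55), with XAF1 at least 36.7-fold and IFIT5 at least 50-fold above no counts. HLA-B went from 7.83 ± 0.558 to 361 ± 13.1 CPM (5.53 ± 0.072, 1.1e-45), and NLRC5 (4.94 ± 0.090, 1.9e-37), TAP1 (4.92 ± 0.061, 2.0e-46), PSMB9 (3.28 ± 0.080, 2.5e-34) and B2M (1.63 ± 0.040, 4.9e-34) rose. Among 20 measured MHC class I genes, 19 rose, 0 fell and 1 did not pass (19 and 0 over the list alone, camera adjusted p = 5.8e-48). The 19 measured MHC class II genes gave 13 that rose, 0 that fell and 6 that did not pass (14 and 0 over the list alone, camera adjusted p = 1.2e-21). CIITA (0.67 ± 0.058, 6.0e-13), HLA-DRB1 (0.89 ± 0.045, 2.3e-21) and HLA-DRB5 (0.98 ± 0.049, 2.2e-21) were among them.

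Some NF-kB, adhesion and apoptosis genes of SU-DHL-4 also rose with CART19. For NF-kB targets, 24 measured, 15 rose, 0 fell and 9 did not pass (18 and 0 over the list alone, camera adjusted p = 3.1e-21). BCL2A1 (1.88 ± 0.14, 1.4e-14), LTA (1.30 ± 0.098, 7.4e-15) and TNFAIP2, up 95.3-fold (95% counting interval 16.7 to 3800) were among them. Of the 26 measured adhesion and costimulatory ligands, 11 rose, 1 fell and 14 did not pass (11 and 2 over the list alone, camera adjusted p = 1.3e-05). ICAM1 (2.20 ± 0.15, 1.3e-16) and CD58, the ligand of CD2, up 33.7-fold (95% counting interval 5.66 to 1370), were among them. CD58 did not pass without DMSO UTD replicate 3 (adjusted p = 0.0502). Among 13 measured inhibitory ligands and receptors, 4 rose, 0 fell and 9 did not pass (5 and 1 over the list alone, camera adjusted p = 4.0e-04), with TNFRSF14 (1.83 ± 0.094, 4.1e-21) and LGALS9 (2.03 ± 0.28, 2.4e-07), and CD274 (0.66 ± 0.88, 0.784) did not pass. The 29 measured death receptor and apoptosis regulators gave 11 that rose, 2 that fell and 16 that did not pass (13 and 2 over the list alone, camera adjusted p = 3.4e-05). FAS (0.83 ± 0.17, 5.6e-04) and PIM2 (0.97 ± 0.096, 4.4e-11) were higher. For plasma cell program genes, 24 measured, 7 rose, 1 fell and 16 did not pass (8 and 1 over the list alone, camera adjusted p = 0.0040). SLAMF7 (3.36 ± 0.60, 4.9e-05) and IRF4, up 67.5-fold (95% counting interval 11.7 to 2700) were among them. Of the 18 measured homing and migration receptors, 5 rose, 0 fell and 13 did not pass (9 and 0 over the list alone, camera adjusted p = 3.4e-04). The activation marker CD83 (0.99 ± 0.078, 4.0e-14) rose, and BCL6 (-0.026 ± 0.045, 0.842) did not pass.

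**Figure D3:**
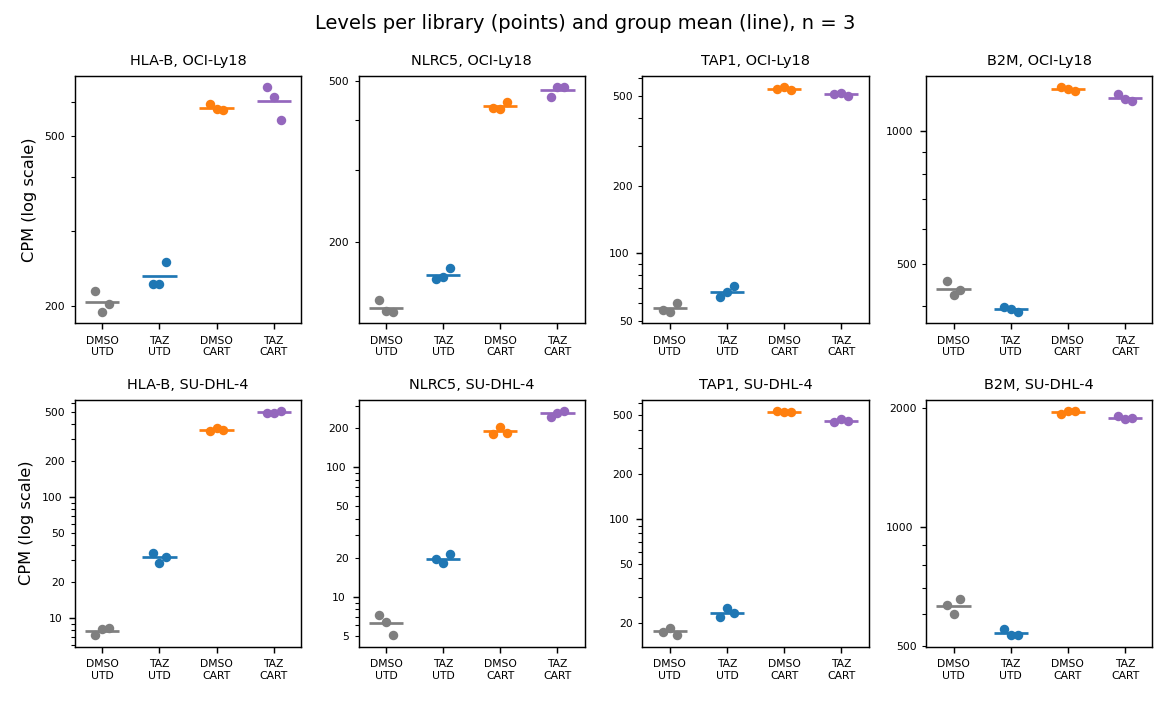
Levels in CPM on a log axis of genes of antigen presentation per library (points) with the mean of 3 libraries (line), for the 4 groups of each line. HLA-B in SU-DHL-4 had means of 7.83, 31.8, 361 and 502 CPM in DMSO UTD, TAZ UTD, DMSO CART19 and TAZ CART19.

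Under tazemetostat, CART19 raised 1372 genes and lowered 832 in OCI-Ly18. Upper quartile scaling gave 1053 and 1175, 47.3% in place of 62.3% rising, and removing trends with length and GC content gave 51.3%. SLFN12L rose at least 165-fold from a group with no counts, and GBP4 (9.34 ± 0.10, 1.6e-35), GBP1 (9.27 ± 0.11, 3.5e-35), GBP2 (8.67 ± 0.29, 5.7e-22), EPSTI1 (6.84 ± 0.30, 2.1e-18) and APOL6 (5.44 ± 0.10, 3.8e-29) rose. The largest decreases were SERINC2 (-1.45 ± 0.35, 0.0037), LRFN2 (-1.41 ± 0.26, 2.0e-04), ADGRB2 (-1.35 ± 0.18, 1.3e-06) and ALKAL2 (-1.26 ± 0.18, 4.4e-06). Among 21 measured MHC class I genes, 21 rose and 0 fell (21 and 0 over the list alone, camera adjusted p = 6.8e-38). TAP1 (2.91 ± 0.053, 2.0e-29), PSMB9 (2.23 ± 0.070, 1.3e-22) and B2M (1.60 ± 0.043, 1.3e-24) were among them. HLA-DQA1 (1.14 ± 0.054, 1.5e-17) of class II rose. The 34 measured interferon gamma response genes gave 31 that rose, 0 that fell and 3 that did not pass (31 and 0 over the list alone, camera adjusted p = 5.1e-53). IRF1 (2.95 ± 0.065, 5.2e-27) was among them. For NF-kB targets, 25 measured, 13 rose, 0 fell and 12 did not pass (16 and 0 over the list alone, camera adjusted p = 4.6e-10), with ICAM1 (2.33 ± 0.16, 3.8e-13) and BCL3 (1.91 ± 0.13, 3.4e-13), and FAS (1.73 ± 0.13, 6.6e-12) rose. Of the 27 measured B cell identity genes, 13 rose, 3 fell and 11 did not pass (16 and 3 over the list alone, camera adjusted p = 4.9e-05). BANK1 (1.75 ± 0.17, 2.6e-09) and MS4A1 (0.59 ± 0.048, 1.9e-11) were among them. Among 39 measured G1/S and DNA replication genes, 0 rose, 6 fell and 33 did not pass (0 and 8 over the list alone, camera adjusted p = 4.9e-04). E2F2 (-0.54 ± 0.054, 3.3e-09) was among them. HMGCS1 (0.44 ± 0.057, 6.4e-07) of cholesterol synthesis rose.

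In SU-DHL-4 under tazemetostat, CART19 raised 989 genes and lowered 1168. Increases were more numerous with only the groups compared (956 and 885), without TAZ CART19 replicates 1 and 2, added after seeing the data (704 and 619), and without DMSO UTD replicate 1 (1068 and 1060) or 3 (1071 and 1051), TAZ UTD replicate 1 (804 and 715) or 3 (782 and 756), DMSO CART19 replicate 1 (1045 and 962), 2 (1035 and 943) or 3 (1004 and 980) or TAZ CART19 replicate 2 (1214 and 1089). GBP4 rose at least 363-fold and XAF1 at least 99.2-fold from groups with no counts, CCL25 417-fold (95% counting interval 115 to 3450) and IFI44L 360-fold (95% counting interval 64.2 to 14300), and GBP1 (7.94 ± 0.15, 5.9e-39) and APOL6 (5.96 ± 0.13, 8.9e-33) rose. The largest decreases were HEMGN (-2.23 ± 0.29, 6.8e-08), TNFRSF10D (-1.48 ± 0.27, 6.8e-05), SPP1 (-1.10 ± 0.086, 2.4e-14) and CELSR2 (-1.02 ± 0.13, 3.4e-08), where TNFRSF10D encodes a decoy receptor for TRAIL. The 20 measured MHC class I genes gave 18 that rose, 0 that fell and 2 that did not pass (18 and 0 over the list alone, camera adjusted p = 6.5e-37). TAP1 (4.29 ± 0.058, 1.2e-44), HLA-B (3.98 ± 0.061, 9.1e-43), NLRC5 (3.73 ± 0.076, 1.7e-35) and PSMB9 (3.37 ± 0.081, 1.3e-34) were among them. HLA-DRB1 (1.0 ± 0.045, 1.6e-23) of class II rose. For interferon gamma response genes, 32 measured, 26 rose, 0 fell and 6 did not pass (27 and 0 over the list alone, camera adjusted p = 4.1e-40). IRF1 (3.98 ± 0.12, 1.9e-14) was among them. Of the 24 measured NF-kB targets, 16 rose, 1 fell and 7 did not pass (18 and 2 over the list alone, camera adjusted p = 4.4e-15), with BIRC3 (1.57 ± 0.12, 4.0e-15) and EBI3, up at least 66.6-fold. ICAM1 (1.96 ± 0.15, 1.8e-14) and FAS (1.33 ± 0.17, 3.6e-08) rose, IRF4 rose 34.3-fold (95% counting interval 5.76 to 1390), and the proliferation genes CENPF (-0.44 ± 0.053, 1.1e-08) and MKI67 (-0.36 ± 0.044, 1.8e-08) fell. Without TAZ CART19 replicates 1 and 2, a setting chosen after seeing the data, 1323 genes changed in place of 2157.

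In OCI-Ly18 the CART19 effect differed between drug and vehicle (interaction term) for 69 genes, 55 higher and 14 lower with tazemetostat. With upper quartile scaling 43 were higher and 22 lower, 66.2% in place of 79.7%. The count depended on other choices as well: 183 higher and 123 lower with no filter, 166 and 72 with DESeq2, 38 and 5 with limma voom, 96 and 30 with all 24 libraries in one fit, and, in settings added after seeing the data, 22 and 3 with the replicate number as a block and 226 and 149 without TAZ CART19 replicates 1 and 2. The largest positive terms were APOL6 (1.26 ± 0.15, 2.0e-05), USP53 (0.69 ± 0.16, 0.0359), BIRC3 (0.65 ± 0.12, 0.0084) and TAGAP (0.63 ± 0.13, 0.0137), where BIRC3 encodes an apoptosis inhibitor induced by NF-kB. The largest negative terms were FRY (-1.02 ± 0.19, 0.0084), IL11RA (-0.97 ± 0.22, 0.0327), ANO9 (-0.93 ± 0.22, 0.0446) and MVP (-0.84 ± 0.19, 0.0414). MS4A1 (0.39 ± 0.067, 0.0037) had a positive term. Among 25 measured NF-kB targets, 1 was higher, 0 were lower and 24 did not pass (6 and 0 over the list alone, camera adjusted p = 0.0045, adjusted p = 0.127 with an estimated correlation), a call lost without TAZ CART19 replicate 2 (adjusted p = 0.0606). The 34 measured unfolded protein and integrated stress response genes gave 0 that were higher, 0 that were lower and 34 that did not pass (0 and 3 over the list alone, camera adjusted p = 0.0045, adjusted p = 0.254 with an estimated correlation). For mitochondrially encoded mRNAs, 13 measured, 0 were higher, 0 were lower and 13 did not pass (6 and 0 over the list alone, camera adjusted p = 2.5e-04, adjusted p = 0.271 with an estimated correlation). The count was 154, 23 and 28 without DMSO UTD replicates 1, 2 and 3, 31 without TAZ UTD replicate 3, 32 and 15 without DMSO CART19 replicates 1 and 3, and 30, 982 and 39 without TAZ CART19 replicates 1, 2 and 3. With 1 library left out (replicate number and adjusted p given), calls of these genes changed. USP53 lost its call without DMSO UTD 2 (0.112) and 3 (0.0710), TAZ UTD 2 (0.0805) and 3 (0.117), DMSO CART19 1 (0.10) and 3 (0.149), TAZ CART19 1 (0.137) and 3 (0.0966). The call of BIRC3 was lost without DMSO CART19 3 (0.0598). TAGAP did not pass without DMSO UTD 3 (0.0600), DMSO CART19 3 (0.0628). IL11RA lost its call without DMSO UTD 1 (0.0526) and 2 (0.114), TAZ UTD 2 (0.0917) and 3 (0.0654), DMSO CART19 1 (0.143) and 3 (0.112), TAZ CART19 1 (0.0974) and 3 (0.0717). The call of ANO9 was lost without DMSO UTD 2 (0.184) and 3 (0.134), TAZ UTD 2 (0.104) and 3 (0.132), DMSO CART19 1 (0.118), 2 (0.0918) and 3 (0.104), TAZ CART19 1 (0.132) and 3 (0.121). MVP did not pass without DMSO UTD 1 (0.0784) and 3 (0.115), TAZ UTD 1 (0.0945) and 3 (0.0666), DMSO CART19 1 (0.115), 2 (0.0553) and 3 (0.146), TAZ CART19 1 (0.131) and 3 (0.0620).

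In SU-DHL-4 the interaction term passed for 133 genes, 40 higher and 93 lower with tazemetostat. It was 102 and 155 with DESeq2, 12 and 51 with all 24 libraries in one fit, and 104 and 88 without TAZ CART19 replicates 1 and 2, added after seeing the data. HLA-B had a term of -1.54 ± 0.097, 5.6e-16: the drug raised it from 7.83 ± 0.558 to 31.8 ± 3.09 CPM with UTD cells and from 361 ± 13.1 to 502 ± 12.3 with CART19. Its level in CPM was highest in TAZ CART19, so the negative term does not mean a lower level with the drug. The other large negative terms were FCER2 (-2.36 ± 0.32, 7.7e-06), NLRC5 (-1.21 ± 0.13, 1.9e-08) and PARP9 (-1.13 ± 0.26, 0.0186), and TAP1 (-0.63 ± 0.083, 5.9e-06) and LTA (-0.77 ± 0.14, 0.0014) were also negative. SOCS1 (-0.88 ± 0.13, 3.1e-05), which encodes a feedback inhibitor of cytokine signalling and was chosen after its value was seen, had a negative term. The largest positive terms were COPS9 (0.61 ± 0.14, 0.0162), CERKL (0.55 ± 0.13, 0.0219), RPS15 (0.49 ± 0.068, 3.1e-05) and MND1 (0.47 ± 0.12, 0.0404). Of the 20 measured MHC class I genes, 1 was higher, 3 were lower and 16 did not pass (3 and 4 over the list alone, camera adjusted p = 0.125). Among 13 measured mitochondrially encoded mRNAs, 0 were higher, 0 were lower and 13 did not pass (1 and 0 over the list alone, camera adjusted p = 0.0055, adjusted p = 0.628 with an estimated correlation), a call lost without DMSO UTD replicate 2 (adjusted p = 0.123) or TAZ CART19 replicate 1 (adjusted p = 0.0790). The count was 70 and 63 without DMSO UTD replicates 1 and 3, 66, 75 and 37 without TAZ UTD replicates 1, 2 and 3, 74, 54 and 44 without DMSO CART19 replicates 1, 2 and 3, and 414 and 82 without TAZ CART19 replicates 2 and 3. Higher terms then outnumbered lower ones without DMSO UTD replicate 1 (40 and 30), TAZ UTD replicate 1 (34 and 32) and DMSO CART19 replicates 1 (38 and 36) and 3 (24 and 20). The 93 genes, which were picked as lower, had a median log2 term of -0.357 with all libraries and of -0.384 to -0.304 with 1 left out, so calls were lost while this median moved little. COPS9 lost its call without DMSO UTD 3 (0.0739), TAZ UTD 2 (0.0539), DMSO CART19 2 (0.102). The call of CERKL was lost without DMSO UTD 1 (0.0520) and 3 (0.0782), TAZ UTD 2 (0.0689) and 3 (0.0733), DMSO CART19 2 (0.0807) and 3 (0.0533), TAZ CART19 3 (0.0757). MND1 did not pass without DMSO UTD 1 (0.0553) and 3 (0.106), TAZ UTD 2 (0.10) and 3 (0.136), DMSO CART19 1 (0.0567) and 3 (0.139), TAZ CART19 3 (0.128). PARP9 lost its call without DMSO UTD 1 (0.0876) and 3 (0.106), TAZ UTD 1 (0.134) and 3 (0.0832), DMSO CART19 2 (0.0672) and 3 (0.0567).

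The lines differed in their response to tazemetostat with UTD cells for 1875 of 17766 genes, 1225 with a higher effect in SU-DHL-4 and 650 with a lower one. HLA-B and BACH2, chosen after their values were seen, had differences (SU-DHL-4 minus OCI-Ly18) of 1.84 ± 0.10, 1.7e-17 and 2.98 ± 0.099, 2.7e-26, and NLRC5 (1.42 ± 0.11, 3.9e-13), CDKN1A (1.35 ± 0.18, 6.6e-07) and MS4A1 (0.47 ± 0.067, 1.1e-06) were also higher. MYC (-0.54 ± 0.058, 2.1e-09) rose more in OCI-Ly18. The 39 measured G1/S and DNA replication genes gave 0 that were higher in SU-DHL-4, 11 that were lower and 28 that did not pass (0 and 16 over the list alone, camera adjusted p = 1.2e-07). E2F2 (-0.43 ± 0.073, 2.3e-05), CDT1 (-0.38 ± 0.095, 0.0043) and GINS2 (-0.37 ± 0.10, 0.0093) were among them. For MYC targets, 31 measured, 0 were higher in SU-DHL-4, 7 were lower and 24 did not pass (0 and 14 over the list alone, camera adjusted p = 2.2e-06). LYAR (-0.47 ± 0.095, 3.6e-04) and FBL (-0.38 ± 0.071, 1.7e-04) were among them. Of the 28 measured B cell identity genes, 11 were higher in SU-DHL-4, 4 were lower and 13 did not pass (13 and 7 over the list alone, camera adjusted p = 0.0083, adjusted p = 0.0579 with an estimated correlation). The largest differences were of genes nearly silent in a group, given as counts with DMSO and with tazemetostat in OCI-Ly18, the same in SU-DHL-4: CNTNAP2 (429, 282, 0, 12, adjusted p = 0.0099), NPAS2 (542, 187, 0, 6, adjusted p = 0.0187), MVB12B (186, 267, 0, 26, adjusted p = 0.0024), CD163L1 (299, 281, 0, 15, adjusted p = 0.0014), HOXA7 (0, 12, 271, 319, adjusted p = 0.0104), JAG2 (0, 12, 398, 545, adjusted p = 0.0216), ADGRE5 (3, 100, 1060, 1278, adjusted p = 1.8e-07) and LAMA5 (3, 61, 5040, 5263, adjusted p = 1.2e-06). NPAS2 did not pass without SU-DHL-4 TAZ UTD replicate 2 (adjusted p = 1.0), and JAG2 without OCI-Ly18 DMSO UTD replicate 1 (adjusted p = 0.0615), 2 (adjusted p = 0.0574) or 3 (adjusted p = 0.0678) or TAZ UTD replicate 3 (adjusted p = 0.0660). Higher effects made up 65.3% of the differing genes, 44.6% with trends with length and GC content removed and 51.1% (1063 against 1019) without OCI-Ly18 TAZ CART19 replicate 2.

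The CART19 effect under DMSO differed between the lines for 502 genes, 212 higher and 290 lower in SU-DHL-4. Higher ones were more numerous with a stricter filter (256 and 225), without TAZ CART19 replicates 1 and 2 of both lines, added after seeing the data (348 and 318), and without OCI-Ly18 DMSO UTD replicate 3 (176 and 162), DMSO CART19 replicate 2 (200 and 171) or 3 (180 and 160), or SU-DHL-4 TAZ UTD replicate 1 (218 and 213) or 2 (223 and 212) or TAZ CART19 replicate 1 (243 and 239) or 3 (224 and 222). Class I genes stood out: HLA-B (4.01 ± 0.097, 7.3e-32), NLRC5 (3.28 ± 0.10, 9.2e-28) and TAP1 (1.67 ± 0.076, 3.2e-21), and among 21 measured MHC class I genes, 6 were higher in SU-DHL-4, 2 were lower and 13 did not pass (9 and 2 over the list alone, camera adjusted p = 4.9e-07). IRF1 (1.04 ± 0.14, 4.7e-06), NFKB2 (1.09 ± 0.15, 3.0e-06), CD83 (0.90 ± 0.12, 5.0e-07) and NFKBIA (0.80 ± 0.17, 0.0024) were higher in SU-DHL-4, and FAS (-1.12 ± 0.22, 0.0013), PDIA4 (-0.55 ± 0.062, 2.3e-08) and FRY (-6.50 ± 0.75, 3.0e-08) lower. The 28 measured NF-kB targets gave 5 that were higher in SU-DHL-4, 0 that were lower and 23 that did not pass (5 and 2 over the list alone, camera adjusted p = 0.0237), a call lost with a stricter filter (adjusted p = 0.226). For unfolded protein and integrated stress response genes, 34 measured, 1 was higher in SU-DHL-4, 9 were lower and 24 did not pass (2 and 13 over the list alone, camera adjusted p = 5.8e-07). Of the 28 measured B cell identity genes, 0 were higher in SU-DHL-4, 7 were lower and 21 did not pass (0 and 9 over the list alone, camera adjusted p = 0.0048). Genes nearly silent in a group, given as counts with UTD and CART19 cells in OCI-Ly18, the same in SU-DHL-4, were IFIT5 (726, 1621, 0, 151, adjusted p = 4.6e-09), MX2 (5919, 5827, 0, 32, adjusted p = 9.4e-05), IRF4 (6210, 5029, 1, 68, adjusted p = 8.8e-09), SAMD9L (164, 999, 2, 474, adjusted p = 1.5e-08), PKHD1L1 (0, 14, 464, 508, adjusted p = 0.0390), CXCR5 (1, 62, 267, 359, adjusted p = 3.4e-04) and SLAMF1 (0, 15, 2263, 4066, adjusted p = 0.0225). PKHD1L1 lost its call without OCI-Ly18 DMSO UTD 1 (0.104), 2 (0.119) and 3 (0.139), OCI-Ly18 DMSO CART19 1 (0.0611) and 3 (0.159), SU-DHL-4 DMSO UTD 3 (0.0538), SU-DHL-4 DMSO CART19 1 (0.0565). The call of SLAMF1 was lost without OCI-Ly18 DMSO UTD 1 (0.0830), 2 (0.0938) and 3 (0.112), OCI-Ly18 DMSO CART19 3 (0.147).

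The tazemetostat effect with CART19 cells differed between the lines for 1797 genes, 1051 higher and 746 lower in SU-DHL-4, a split that was 925 to 1020 with RLE scaling (47.6% in place of 58.5%), 968 to 1057 with a stricter filter, 1067 to 1212 with DESeq2, 1263 to 549 with upper quartile scaling (69.7%) and 42.6% with trends with length and GC content removed. Leaving out 1 library turned it for 15 of the 24 libraries, to 834 against 1387 without SU-DHL-4 TAZ CART19 replicate 1 (37.6%) and 947 against 1522 without OCI-Ly18 TAZ CART19 replicate 2 (38.4%), so which direction prevails depends on these choices and on single libraries. CDKN1A (1.34 ± 0.18, 4.3e-07) had a higher effect in SU-DHL-4, and E2F2 (-0.45 ± 0.074, 1.9e-05), RRM2 (-0.32 ± 0.080, 0.0060), MYC (-0.64 ± 0.058, 3.9e-11), POLR3G (-0.41 ± 0.11, 0.0101) and NFKB2 (-0.82 ± 0.15, 1.0e-04) a lower one. Among 39 measured G1/S and DNA replication genes, 0 were higher in SU-DHL-4, 8 were lower and 31 did not pass (0 and 11 over the list alone, camera adjusted p = 2.7e-05). The 31 measured MYC targets gave 0 that were higher in SU-DHL-4, 6 that were lower and 25 that did not pass (0 and 7 over the list alone, camera adjusted p = 4.2e-04). For inhibitory ligands and receptors, 15 measured, 4 were higher in SU-DHL-4, 1 was lower and 10 did not pass (5 and 2 over the list alone, camera adjusted p = 0.0345, adjusted p = 0.0835 with an estimated correlation), a call also lost with a stricter filter (adjusted p = 0.131). Of the 28 measured NF-kB targets, 2 were higher in SU-DHL-4, 8 were lower and 18 did not pass (2 and 10 over the list alone, camera adjusted p = 0.0253), a call lost without OCI-Ly18 TAZ CART19 replicate 2 (adjusted p = 0.0539) or SU-DHL-4 TAZ CART19 replicate 1 (adjusted p = 0.0591). Genes nearly silent in a group, given as counts with DMSO and tazemetostat in each line in the same order, were BTBD3 (773, 940, 0, 83, adjusted p = 3.9e-08), SLC16A10 (765, 987, 0, 24, adjusted p = 0.0046), KIF5A (664, 945, 1, 98, adjusted p = 1.9e-08), ZNF618 (1665, 2306, 0, 19, adjusted p = 0.0211), ZNF423 (98, 317, 7, 0, adjusted p = 0.0067), FAAH (958, 951, 11, 0, adjusted p = 0.0301), INF2 (0, 10, 4231, 4341, adjusted p = 0.0149) and RNF130 (204, 700, 7, 1, adjusted p = 0.0134). ZNF618 lost its call without SU-DHL-4 DMSO CART19 1 (0.0612), 2 (0.0702) and 3 (0.0630), SU-DHL-4 TAZ CART19 3 (0.0603). The call of FAAH was lost without SU-DHL-4 DMSO CART19 1 (0.232), SU-DHL-4 TAZ CART19 1 (0.0677), 2 (0.0710) and 3 (0.0573). INF2 did not pass without OCI-Ly18 TAZ CART19 3 (0.130). RNF130 lost its call without SU-DHL-4 DMSO CART19 2 (0.0600) and 3 (0.141).

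Across genes, the tazemetostat effect with UTD cells correlated with that with CART19 cells, 2 contrasts that share no library, at a Pearson r of 0.509 over 16467 genes in OCI-Ly18 and 0.672 over 14861 in SU-DHL-4, and at 0.726 and 0.866 among genes with a mean of at least 5 CPM. The CART19 effect under DMSO correlated with that under tazemetostat at 0.550 and 0.568, and at 0.801 and 0.853 among the better expressed genes. Between the lines, over 13778 genes, r was 0.358 for tazemetostat with UTD cells, 0.341 for tazemetostat with CART19, 0.462 for CART19 under DMSO and 0.500 under tazemetostat, and 0.457, 0.481, 0.719 and 0.690 in this order among genes with a mean of at least 5 CPM. CART19 under DMSO raised 365 genes in both lines, against 43.7 by chance, and tazemetostat with UTD cells raised 738 in both, against 257. Genes are not independent replicates, so no p is given for these values.

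**Figure D4:**
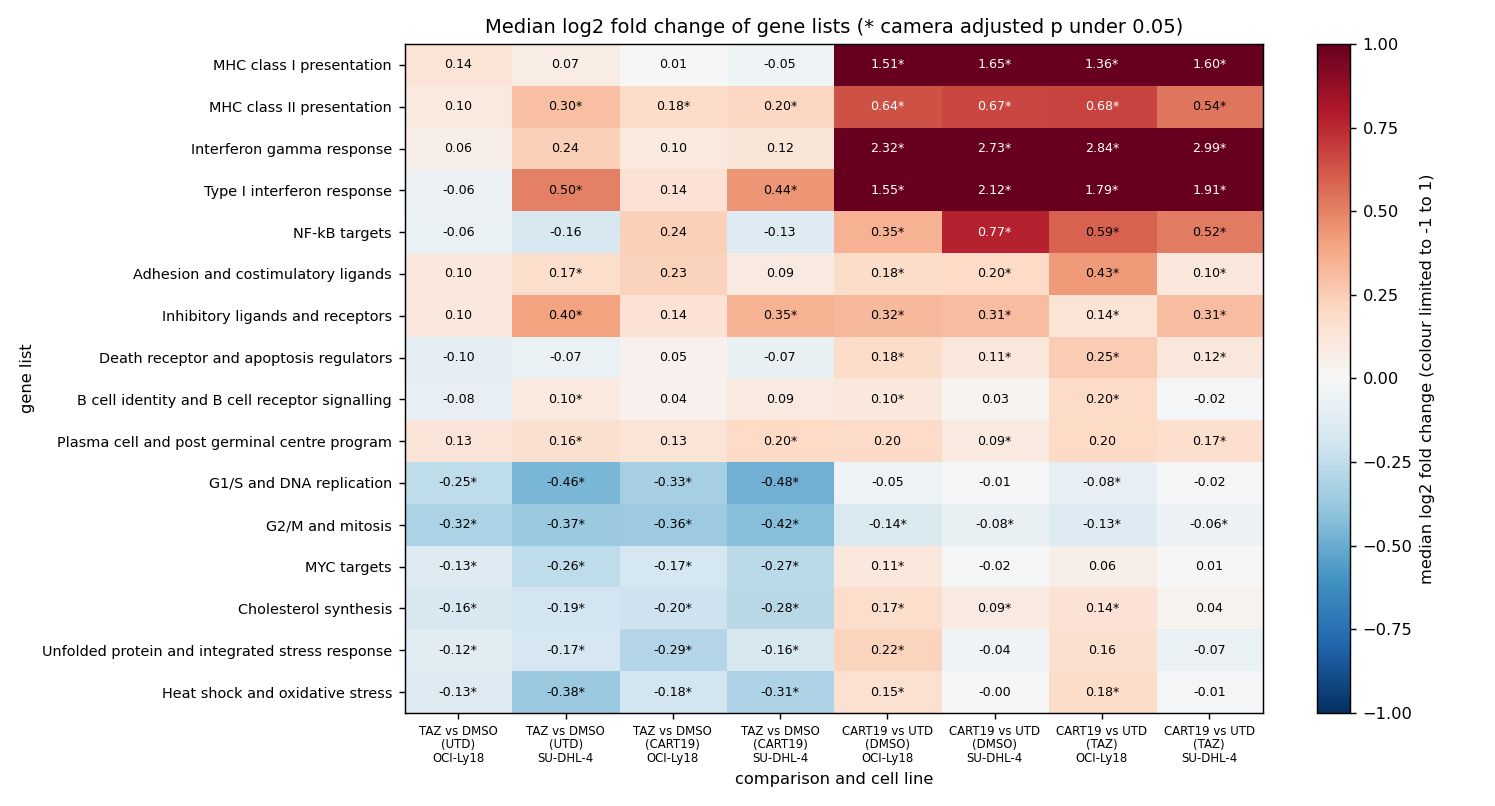
Median log2 fold change of each gene list (rows) in each comparison and line (columns), with the colour limited to -1 to 1 and a star for a camera adjusted p under 0.05. The interferon gamma response list had medians of 2.32 in OCI-Ly18 and 2.73 in SU-DHL-4 with CART19 under DMSO, and the G1/S and DNA replication list -0.25 and -0.46 with tazemetostat and UTD cells.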

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

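The tests and regroupings of libraries here were chosen after the results were seen. RLE and upper quartile scaling and leaving out 1 library had been planned. Interferon response genes were higher with CART19 than with UTD cells. RNA from T cells left in the sort could bring such transcripts, which these values do not decide. With CART19, CD3D, CD3G, CD2 and CD7, chosen after their values were seen, reached 0.0765 CPM at most. IFNG reached 1.54 CPM in SU-DHL-4 TAZ CART19. The scaling, or a bias with gene length or GC content, might also raise them, but 100% of the rising interferon gamma list genes still rose with RLE or upper quartile scaling and 100% after the trends with length and GC content were removed. The IFNG and GZMB counts with CART19 may come from a few T cells, and which signal reached the tumour cells stays open.

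Changes of at least 1 log2 with tazemetostat were mostly increases. Low counts with DMSO, where only an increase can be large, may account for most of these. With UTD cells 91 of 554 increases in OCI-Ly18 and 140 of 1006 in SU-DHL-4 had at least 5 CPM with DMSO. Among such genes the lowest share of increases was 78.2% with TMM. Over all tested genes it was 86% with RLE or upper quartile scaling and 85.3% with a line's libraries thinned to one total. With at least 5 CPM these were 77.8% and 77.9%. Loss of repression by EZH2 is a hypothesis whose test needs histone methylation data, not used here. A change in total RNA per cell, which scaling removes, stays open.

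In SU-DHL-4, the CART19 effect on 93 genes, as a log2 fold change, was lower with tazemetostat than with DMSO. A bias with gene length or GC content could produce such lower terms. With those trends removed the median term of the 93 went from -0.357 to -0.282 and 69 kept their call. The bias, as these trends describe it, may thus account for part of the terms, but not for those 69 calls. Of the 188 terms that then passed, 119 were lower (63.3%, 95% counting interval 56 to 70.2). Counting intervals here treat genes as independent, which they are not, so this share does not decide. A single library might also produce lower terms, but at least 20 genes had one past the threshold whichever library was left out, and 17 had it each time. Whether lower terms outnumber higher ones stays open: their share was 42.9% (95% counting interval 31.1 to 55.3) without DMSO UTD replicate 1 and also under 50% without TAZ UTD replicate 1 or DMSO CART19 replicates 1 or 3, each with an interval that spans 50%. HLA genes made up 1.08% of the set, too few for shared reads to account for it, while shared reads for HLA-B alone, and a level already raised by the drug that may leave less room for CART19 to act, were not tested.

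Libraries were also regrouped within each comparison in all ways that keep group sizes. A comparison of 2 groups allows 10 splits, so the share of splits with as many genes cannot be under 0.05. The real split alone reached its count in each of the 8 (1 of 10), and the highest other split gave 1 gene for CART19 under tazemetostat in OCI-Ly18, and for CART19 under DMSO and under tazemetostat in SU-DHL-4, and 0 elsewhere. For the interaction, 2 of 100 splits reached 69 genes in OCI-Ly18 (highest other 104) and 1 of 100 reached 133 in SU-DHL-4 (highest other 3). For the differences between the lines it was 1 of 100 each, with highest others of 1470 for tazemetostat with UTD cells, 253 for CART19 under DMSO and 1768 for tazemetostat with CART19. The splits behind 104, 1470, 253 and 1768 mixed libraries in 1 arm only, and those mixed in both arms gave at most 1, 1, 2 and 2 genes. A mixed arm moves its drug or CART19 effect into the spread within groups, and an arm left whole keeps its effect. Such splits do not show what an absent interaction or line difference would give, so the shares of 100 cannot decide.

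Each value that follows was set apart because a test of the difference between groups passed. The tazemetostat effect with UTD cells differed between the lines for 1875 genes. Named genes had log2 differences (SU-DHL-4 minus OCI-Ly18) of APOL6 1.17, ASB2 1.39, BACH2 2.98, CD24 2.11, CD27 1.53, CDC45 -0.35, CDKN1A 1.35, CDT1 -0.38, CEACAM1 3.38, E2F2 -0.43, FBL -0.38, FCGR2B 1.99, GINS2 -0.37, HLA-B 1.84, HLA-DOA 0.39, JAM2 3.38, LRP5 -2.44, LYAR -0.47, MEF2C -1.14, MS4A1 0.47, MYC -0.54, NLRC5 1.42, NME4 -2.91, SERPINA9 -2.12, SESN1 1.43, SLC25A29 -1.99, SOX2 -1.85 and SUSD3 1.91. For genes nearly silent in a group the adjusted p was: ADGRE5 1.8e-07, CD163L1 0.0014, CD44 0.0014, CNTNAP2 0.0099, HOXA7 0.01, JAG2 0.022, LAMA5 1.2e-06, MVB12B 0.0024 and NPAS2 0.019. Differing lists had median log2 differences of B cell identity 0.24, MHC class II 0.19, interferon gamma response 0.23, G1/S -0.15, hypoxia and glycolysis -0.07 and MYC targets -0.18. The list of hypoxia and glycolysis had a mean of 0.059, and several lists lost their calls at adjusted p: B cell identity (0.0579 with an estimated correlation), MHC class II (0.0866 with an estimated correlation), interferon gamma response (0.0727 with an estimated correlation, 0.0522 without OCI-Ly18 DMSO UTD 1, 0.0590 without SU-DHL-4 DMSO UTD 3, 0.0604 without SU-DHL-4 TAZ UTD 2), hypoxia and glycolysis (0.0866 with an estimated correlation, 0.0522 without OCI-Ly18 DMSO UTD 1, 0.0520 without SU-DHL-4 DMSO UTD 2, 0.0590 without SU-DHL-4 DMSO UTD 3, 0.0634 without SU-DHL-4 TAZ UTD 3).

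The CART19 effect under DMSO differed between the lines for 502 genes. Named genes had log2 differences of BANK1 -1.07, CD83 0.90, DHCR7 -0.35, EPSTI1 -1.75, FAS -1.12, FRY -6.50, HLA-B 4.01, HLA-DQA1 -0.25, IRF1 1.04, LGALS3BP 1.38, MVD -0.40, NFKB2 1.09, NFKBIA 0.80, NLRC5 3.28, PDIA4 -0.55, PIM2 -0.45, PSMB9 0.90, PTPN6 -1.61, TAP1 1.67 and TNFRSF14 -2.39. Adjusted p for genes nearly silent in a group: CD58 0.0028, CXCR5 0.00034, IFIT5 4.6e-09, IRF4 8.8e-09, MX2 9.4e-05, PKHD1L1 0.039, SAMD9L 1.5e-08, SLAMF1 0.022 and XAF1 0.041. Median log2 differences of lists: B cell identity -0.11, MHC class I 0.18, NF-kB targets 0.09, cholesterol synthesis -0.11, unfolded protein response -0.21, hypoxia and glycolysis -0.19, heat shock -0.16 and MYC targets -0.16. Among these, some lost their calls at adjusted p: NF-kB targets (0.226 with a stricter filter), cholesterol synthesis (0.0854 with an estimated correlation, 0.0550 with RLE scaling, 0.116 with a stricter filter, 0.0517 to 0.119 without 1 of 17 libraries). The tazemetostat effect with CART19 cells differed for 1797 genes, with log2 differences of ANXA4 2.48, ASB2 1.23, ATF5 0.54, BACH2 3.15, BTG2 -0.45, CD27 1.51, CDKN1A 1.34, CORO2A 2.03, E2F2 -0.45, HLA-B 0.44, HLA-C 0.51, HLA-DOA 0.22, HMGCS1 -0.38, IFI6 1.17, JAM2 3.03, LGALS9 0.96, LRP5 -2.34, MYC -0.64, NDUFA4L2 1.24, NFKB2 -0.82, NLRC5 0.35, NME4 -2.84, POLR3G -0.41, RRM2 -0.32, SERPINA9 -2.35, SESN1 1.44, SGK1 -1.57, TP53INP1 -0.67 and TYMS -0.30. Adjusted p for genes nearly silent in a group: BTBD3 3.9e-08, FAAH 0.03, INF2 0.015, KIF5A 1.9e-08, RNF130 0.013, SLC16A10 0.0046, VSIR 0.005, ZNF423 0.0067 and ZNF618 0.021. Median log2 differences of lists: inhibitory ligands 0.59, NF-kB targets -0.20, G1/S -0.12 and MYC targets -0.12. Here too some lost their calls at adjusted p: inhibitory ligands (0.0835 with an estimated correlation, 0.131 with a stricter filter), NF-kB targets (0.0539 without OCI-Ly18 TAZ CART19 2, 0.0591 without SU-DHL-4 TAZ CART19 1).

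The interaction of tazemetostat and CART19 passed for 69 genes in OCI-Ly18, with log2 terms of ANO9 -0.93, APOL6 1.26, BIRC3 0.65, BTG2 0.40, CD38 0.45, FRY -1.02, IL11RA -0.97, MS4A1 0.39, MVP -0.84, OAS2 0.63, TAGAP 0.63, TAP1 -0.33 and USP53 0.69 and list medians of NF-kB targets 0.20, unfolded protein response -0.15 and mitochondrially encoded mRNAs 0.24. All 3 lists lost their calls with an estimated correlation (adjusted p = 0.127, 0.254 and 0.271 in this order). NF-kB targets also lost theirs without TAZ CART19 2 (0.0606). The interaction passed for 133 genes in SU-DHL-4, with log2 terms of CERKL 0.55, COPS9 0.61, FCER2 -2.36, HLA-B -1.54, LTA -0.77, MND1 0.47, NLRC5 -1.21, PARP9 -1.13, PAX5 -0.46, RPS15 0.49, SOCS1 -0.88, TAP1 -0.63 and TNFRSF14 -0.52 and a list median of mitochondrially encoded mRNAs 0.19, with 0 of 13 members past the threshold. That list lost its call (adjusted p = 0.628 with an estimated correlation, 0.123 without DMSO UTD 2, 0.0790 without TAZ CART19 1).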

How the results depend on the processing

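Alternatives named here as added were chosen after seeing the data. A minimum of 1 log2 on the change left 619, 492, 309, 358 and 4 genes in OCI-Ly18 (tazemetostat with UTD cells, with CART19, CART19 under DMSO, under tazemetostat, interaction), and 1033, 899, 275, 236 and 6 in SU-DHL-4. It left 591, 125 and 554 genes for the differences between the lines in tazemetostat with UTD cells, CART19 under DMSO and tazemetostat with CART19. These counts are lower by construction. The interaction in OCI-Ly18 (69 genes) gave 306 with no filter on low counts, 238 with DESeq2, 43 with limma voom and 126 with all 24 libraries in one fit, and 375 without TAZ CART19 replicates 1 and 2 (added). The authors' replicate number as a block (added) gave 25 there, but libraries with the same number showed no pairing within a line: the correlation of their deviations from the group mean ran from -0.296 to 0.172 over 12 pairs of groups. The interaction in SU-DHL-4 (133 genes) gave 257 with DESeq2 and 63 with all 24 libraries in one fit. CART19 under tazemetostat in SU-DHL-4 gave 1323 without TAZ CART19 replicates 1 and 2 (added), where the lone library left is assumed to vary like the other groups. The cause was not tested in any of these.

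Leaving out 1 library gave ranges, in OCI-Ly18, of 3035 to 4378 for tazemetostat with UTD cells, 2606 to 3887 with CART19, 1187 to 2159 for CART19 under DMSO, 1647 to 2867 under tazemetostat and 15 to 982 for the interaction. In SU-DHL-4 they were 4472 to 5633, 4249 to 5235, 820 to 1438, 1519 to 2303 and 37 to 414, and for the line differences 1517 to 2082 (tazemetostat with UTD cells), 338 to 539 (CART19 under DMSO) and 1461 to 2469 (tazemetostat with CART19). Among 329 results for named genes, 6889 of the alternative values kept direction and side of the threshold, 138 fell short of it (29 results) and 1 reversed: BCL6 with CART19 under DMSO in SU-DHL-4, never past the threshold, ran from -0.0806 without DMSO CART19 replicate 3 to 0.0006171 without replicate 2. Of 138 results for lists, 2427 values kept their call, 109 lost it and 26 gained it, 34 of the losses with an estimated correlation. Of these, 2 losses and 20 gains came with fry, which tests a list against no change rather than against other genes. Of 8 correlations of effects, 7 moved with only genes of at least 5 CPM on average and 6 with only genes past the threshold in either contrast. Depth limits what can be seen of genes with few counts.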

Other observations

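Other fixed lists were measured too. Of the 7 measured CDK inhibitor genes, 1 rose, 3 fell and 3 did not pass (1 and 4 over the list alone, camera adjusted p = 0.380, median -0.27, mean 0.018, test direction down) in SU-DHL-4 with tazemetostat and UTD cells. Among 18 measured homing and migration receptors, 6 rose, 1 fell and 11 did not pass (7 and 1 over the list alone, camera adjusted p = 0.0031) in SU-DHL-4 with CART19 under tazemetostat. The 11 measured T cell marker genes gave 1 that rose, 5 that fell and 5 that did not pass (1 and 6 over the list alone, camera adjusted p = 0.0106) in OCI-Ly18 with CART19 under tazemetostat, and the members that fell had counts in this line with UTD cells as well, TRBC2 with 3477 counts and TRAC with 1020 in its DMSO UTD libraries. For cytotoxic lymphocyte markers, 9 measured, 4 rose, 0 fell and 5 did not pass (4 and 0 over the list alone, camera adjusted p = 0.0347, adjusted p = 0.0700 with an estimated correlation) in SU-DHL-4 with tazemetostat and UTD cells. Of the 3 measured monocyte and macrophage markers, 0 rose, 0 fell and 3 did not pass (0 and 0 over the list alone, camera adjusted p = 0.711) in the same comparison, and 1 erythroid and platelet marker was measured in each line, too few to test.

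Mitochondrially encoded transcripts held 6.93 ± 0.353, 7.0 ± 0.358, 6.30 ± 0.299 and 7.34 ± 0.247 percent of counts (mean ± SD, n = 3) in the OCI-Ly18 groups DMSO UTD, TAZ UTD, DMSO CART19 and TAZ CART19, and 7.40 ± 0.409, 8.26 ± 0.138, 6.70 ± 0.129 and 8.33 ± 0.702 percent in SU-DHL-4. Libraries of the 2 lines with the same replicate number deviated together from their group means in TAZ CART19, with r of 0.343, 0.508 and 0.0540 for numbers 1, 2 and 3 over 9231 genes, and in DMSO UTD number 1 with r of 0.275.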
